A study of Mus musculus with 48 samples.

How the data were processed

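RNA was extracted from the brain hemisphere or the hippocampus of male C57Bl6 mice, and libraries were prepared by a sequencing company from total RNA, per the labels' protocols. The authors deposited FPKM (fragments per kilobase of gene per 1000000 reads) for 54532 genes in 48 libraries as a table of the whole series, with a gene length beside each gene. Per the submitters' processing notes, the genome builds were GRCm38 and mm10 and DESeq 1.10.1 was among the tools; the aligner, the counting tool and its strand setting are not given in the sources used here, so genes that overlap or have near-identical copies are uncertain. Coordinates are those the deposited file gives; 99.93% of its gene identifiers are in GENCODE M21, and 98.33% of those have the same coordinates there. Each value column matched the title of 1 library, and no value column was left unmatched.

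FPKM are not counts, so no count model was used. Each FPKM times the gene's length gave a whole multiple of the value of 1 read for 100% of values (tolerance 0.1 read), which gave the reads in genes per library, 1.21 to 23.5 M (M stands for 1000000). These reads describe depth only. A single read in a gene of 1 kb was worth 0.0399 to 0.0681 FPKM in all libraries but the 6 with few genes. In 5 of these it was worth 0.0635 to 0.0802 FPKM, and in hippocampal replicate 3 of vehicle plus hydralazine 0.722 FPKM, so low genes are imprecise in that library. No pair of libraries of a group agreed within sampling noise (120 pairs, lowest chi-square per gene 3.08 over genes with at least 20 reads). To compare genes detected at equal depth, each library was thinned to 1000000 reads.

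Values were analysed as log2(FPKM + 0.5), a scale that understates the change of low genes. Genes with at least 0.5 FPKM in at least 6 libraries of the fit were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend and a robust prior), with 1 mean per group and all groups of a region sharing the spread; comparisons between regions used all 48 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, two-sided. Comparisons were angiotensin II against vehicle, both drugs against angiotensin II, vehicle and hydralazine alone, hydralazine alone against vehicle, the interaction of the drugs in each region, the hippocampus against the hemisphere in vehicle mice, and the differences between regions of the angiotensin II and hydralazine effects. The 40 gene lists of cell types, pathways, tissue quality and dissection, with 650 genes, were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives. List means per library were compared by two-sided exact permutation tests over the 924 regroupings of 6 against 6, whose smallest p is 0.0022; this test was added after the data were seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.

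The tests, comparisons, lists and alternatives were fixed before the data were examined, unless said otherwise. The rule for named genes took, for angiotensin II against vehicle and for both drugs against angiotensin II, the 10 largest changes in each direction among called protein-coding genes with a symbol that is not a clone name and a mean of at least 1 FPKM in a group; where fewer than 5 genes passed, the 10 such genes with the smallest p were named as not passing. For other comparisons it took 5 in each direction, or the 5 smallest p where fewer than 3 passed. It added up to 4 members of each list that passed, of which the text gives examples, and Agtr1a, Agt, Ace, Gfap, Aif1, Cd68, Cldn5, Cybb, Vcam1, Mbp, Il1b and Ccl2 where tested. Alternatives were pseudocounts of 0.1 and 1, filters at 0.1 and 1 FPKM and none, median-of-ratios and quantile scaling, limma without trend and robust prior, library weights, a choroid plexus covariate, a block for the replicate number, each library left out in turn and fits of only the 2 groups compared. Fits without the 6 hippocampal libraries with fewer than 16000 genes, without angiotensin II replicate 6, and with each library's trend on gene length removed were added after the data were seen. The model fit was tested on simulated reads with the real means, spreads and depths. Between angiotensin II and vehicle 200 genes were changed, and the other ribosomal protein genes tested were raised 1.25-fold. In the hemisphere 61% of genes changed by 1.5-fold and 84% of those changed by 2-fold were recovered among 16949 genes tested, with 8 false calls. In the hippocampus 9% and 32% were recovered among 15567 genes, with 1 false call. Genes were drawn independently, so no shift of a whole library was simulated. The rates hold for this number of changed genes and may be lower where fewer change.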

Results

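Gene expression was measured by RNA sequencing in the brains of male C57Bl6 mice infused for 2 weeks with angiotensin II (0.7 mg per kg per day), the peptide hormone of the renin-angiotensin system that raises blood pressure, or with saline vehicle. Some mice of each kind also drank hydralazine (50 mg per kg), a direct vasodilator used to lower blood pressure. The 4 treatments (vehicle, angiotensin II, vehicle plus hydralazine, angiotensin II plus hydralazine) were each sampled in 2 regions, the brain hemisphere and the hippocampus, with 6 libraries in each of the 8 groups and 48 libraries in all. The design asks which brain genes respond to a hypertensive dose of angiotensin II and whether hydralazine alters that response. Reads assigned to genes, recovered from the deposited FPKM and gene lengths, ranged from 15.77 to 23.5 M per library in the hemisphere (median 18.97 M, where M stands for 1000000). In the hippocampus they ranged from 1.21 to 21 M (median 17.96 M). Hemisphere libraries listed between 23161 and 25610 genes above 0. In the hippocampus 18 libraries listed between 18914 and 23044 genes. The 18914 belonged to replicate 3 of angiotensin II plus hydralazine, and the next lowest of these listed 21042. The remaining 6 libraries listed between 7805 and 15684. These 6 libraries were replicates 3 and 4 of vehicle, replicate 3 of angiotensin II, replicates 3 and 4 of vehicle plus hydralazine and replicate 5 of angiotensin II plus hydralazine. Replicate 6 of angiotensin II stood apart in both regions. Mitochondrial transcripts made up 2.77% of its reads in the hemisphere, against 5.84% to 6.66% in the other 5 libraries of its group. In the hippocampus they made up 5.74%, against 8.91% to 10.01%. The labels do not say that the replicates of a group are separate mice, so p-values measure the spread between these libraries.

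**Figure D1:**
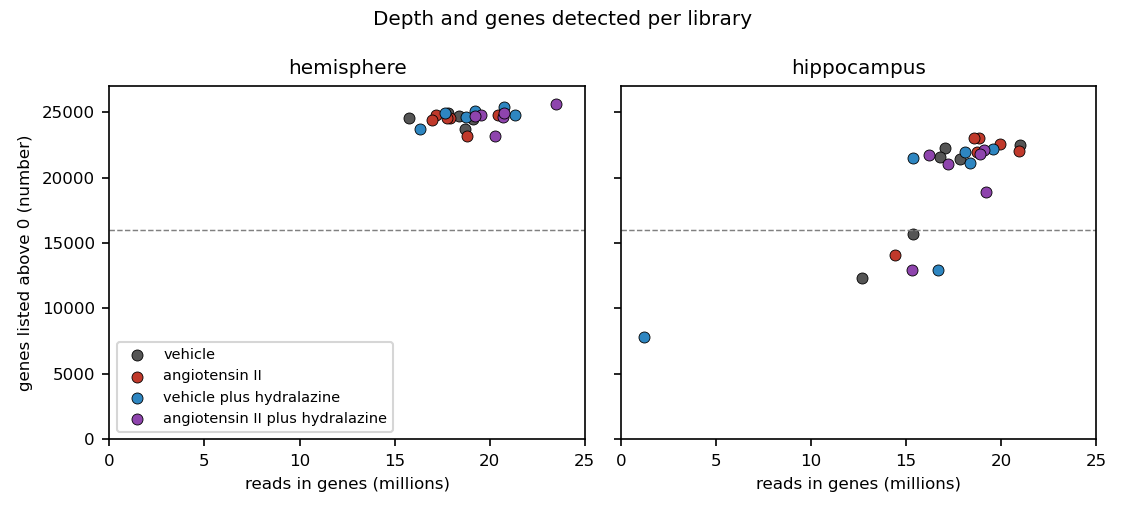
Reads in genes (in units of 1000000, x axis) against the number of genes listed above 0 (y axis) for each library, by region and coloured by treatment; the dashed line marks 16000 genes. The 6 hippocampal libraries below the line list 7805 to 15684 genes, and the 24 hemisphere libraries list 23161 to 25610.

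Angiotensin II was first compared with vehicle in the hemisphere. Of 16747 genes tested with limma, 12 passed an adjusted p of 0.05, with 3 higher and 9 lower under angiotensin II. Before adjustment 1548 had a p under 0.05, where 837 are expected by chance. Genes that neurons switch on within minutes of activity showed the largest falls. Arc, which encodes a synaptic regulator induced by neuronal firing (ENSMUSG00000022602, GRCm38 chromosome 15, 74669083 to 74672570), averaged 24.3 ± 4.99 FPKM under angiotensin II and 90.7 ± 29.6 FPKM under vehicle (mean ± SD, n = 6 each), a log2 fold change of -1.82 ± 0.31 (SE; limma adjusted p = 0.0209). Dusp1, a phosphatase that switches off MAP kinases (chromosome 17, 26505590 to 26508519), fell from 18.6 ± 3.47 to 8.06 ± 1.26 FPKM, with a log2 fold change of -1.15 ± 0.19 (adjusted p = 0.0172). The AP-1 subunit Junb (chromosome 8, 84974484 to 84978718) fell from 35.9 ± 8.51 to 16.1 ± 3.09 FPKM (log2 fold change -1.11). The orphan nuclear receptor gene Nr4a1 (chromosome 15, 101254269 to 101274795) fell from 38.0 ± 9.80 to 18.2 ± 3.52 FPKM (log2 fold change -1.02), and the antiproliferative gene Btg2 (chromosome 1, 134075170 to 134079120) from 9.16 ± 2.07 to 4.73 ± 1.44 FPKM (log2 fold change -0.90). Smaller falls passed for Msantd1 (-0.47), the deubiquitinase gene Otud1 (-0.43), the histone demethylase gene Kdm6b (-0.40) and the beta-1 adrenergic receptor gene Adrb1 (-0.39). Eln, which encodes the elastin of arterial walls (chromosome 5, 134702593 to 134747323), rose from 1.56 ± 0.214 to 2.76 ± 0.717 FPKM (log2 fold change 0.64 ± 0.12, adjusted p = 0.0255). Podxl, which encodes a sialomucin of the endothelial surface (chromosome 6, 31519488 to 31563981), rose from 7.38 ± 0.547 to 9.56 ± 0.614 FPKM (log2 fold change 0.35 ± 0.07, adjusted p = 0.0316). The third gene to rise was the nuclear long noncoding RNA Neat1 (chromosome 19, 5824708 to 5845478), from 6.98 ± 0.718 to 9.61 ± 0.720 FPKM (log2 fold change 0.44). It falls outside the rule for named genes, which takes protein-coding genes, and was named after its values were seen. For each of the 11 protein-coding genes, all 6 angiotensin II libraries lay beyond the vehicle mean in the direction of the change. The genes were picked from these same libraries, so this adds no support. Single libraries of the 2 groups overlapped for Junb, Nr4a1, Btg2, Otud1 and Msantd1. Junb, for example, was 19.6 FPKM in vehicle replicate 3 and 20.17 FPKM in angiotensin II replicate 2. The count was 0 without angiotensin II replicate 4, vehicle replicate 5 or vehicle replicate 6, 3 without vehicle replicate 2, 6 without angiotensin II replicate 5 or vehicle replicate 4, and 20 without vehicle replicate 3. It was 11 without angiotensin II replicate 6, where Junb (log2 fold change -1.06, adjusted p = 0.0655), Nr4a1 (-1.004, adjusted p = 0.125) and Btg2 (-0.82, adjusted p = 0.118) were not called. It was 38 with library weights, 5 with a block for the replicate number and 4 without a filter on low values. It was 2 when only these 2 groups were fitted and 0 with the choroid plexus list mean as a covariate. With that covariate the log2 fold changes were -1.70 ± 0.33 for Arc, -0.92 ± 0.19 for Btg2, 0.62 ± 0.13 for Eln and 0.38 ± 0.07 for Neat1, each with an adjusted p of 0.1.

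**Figure D2:**
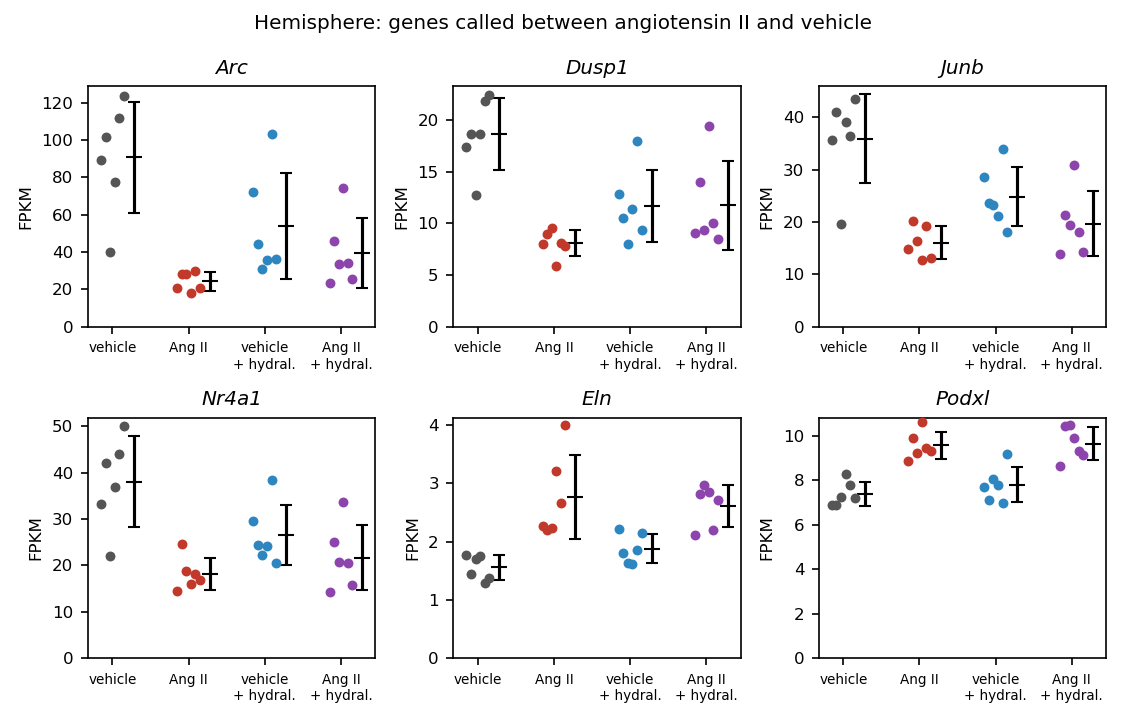
FPKM (y axis, from 0) of 6 genes called between angiotensin II and vehicle in the hemisphere, in each of the 4 treatments; points are libraries and the bar beside them gives the mean ± SD (n = 6). Arc lies at 24.3 ± 4.99 FPKM under angiotensin II against 90.7 ± 29.6 FPKM under vehicle, and Eln at 2.76 ± 0.717 against 1.56 ± 0.214.

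Across gene lists fixed before the data were examined, 15 of 40 passed the camera test for angiotensin II against vehicle in the hemisphere, 9 toward higher and 6 toward lower expression. No list of this contrast passed with an estimated correlation. All 20 immediate early genes had lower values under angiotensin II (median log2 fold change -0.60, adjusted p = 2.44e-22; adjusted p = 0.13 with an estimated correlation). Of them 5 fell over all genes tested and 16 fell when adjusted over the list alone. The mean log2 value of this list per library was 3.55 ± 0.34 under vehicle and 2.84 ± 0.21 under angiotensin II (SD, n = 6; exact permutation p = 0.00866, adjusted over the lists 0.0866). Without angiotensin II replicate 6 this difference was -0.65 (exact permutation p = 0.0108, adjusted over the lists 0.108). Antigen presentation genes were higher in 15 of 16 members (median 0.27, adjusted p = 5.82e-08; adjusted p = 0.326 with an estimated correlation), with no member past the threshold over all genes tested and 5 higher when adjusted over the list alone. The class II gene H2-Eb1 averaged 5.36 ± 4.01 FPKM under angiotensin II and 2.66 ± 0.318 under vehicle (adjusted p = 0.376), and H2-Aa averaged 2.79 ± 1.28 and 1.66 ± 0.261 (adjusted p = 0.429). The list mean of angiotensin II replicate 6 was 3.12, against 2.18 to 2.45 in the other 5 libraries of its group, and the list median was 0.14 without it. Border macrophage genes were higher in all 4 tested members (median 0.23, adjusted p = 0.028; adjusted p = 0.296 with an estimated correlation). Complement genes had a median of 0.13 (adjusted p = 0.0117; adjusted p = 0.326 with an estimated correlation), with C4b, a complement component, at 7.33 ± 2.13 FPKM under angiotensin II and 5.21 ± 0.519 under vehicle (adjusted p = 0.302). Reactive astrocyte genes had a median of 0.10 (adjusted p = 0.00229; adjusted p = 0.303 with an estimated correlation), and extracellular matrix genes a median of 0.12 (adjusted p = 0.00303; adjusted p = 0.486 with an estimated correlation). Lists for lymphocytes and neutrophils (median 0.24; adjusted p = 0.446 with an estimated correlation) and for the interferon response (median 0.09; adjusted p = 0.532 with an estimated correlation) also passed toward higher values. Without angiotensin II replicate 6 the interferon list did not pass (adjusted p = 0.232), and with library weights neither did (adjusted p = 0.0566 and 0.385).

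Lower values were also found for choroid plexus genes, markers of the epithelium that makes cerebrospinal fluid, in 11 of 11 members (median -0.27, adjusted p = 0.000235; adjusted p = 0.526 with an estimated correlation). Circadian clock genes (median -0.11; adjusted p = 0.151 with an estimated correlation), heat shock genes (median -0.22; adjusted p = 0.532 with an estimated correlation) and thalamus and midbrain genes (6 of 12 members lower, median -0.08; adjusted p = 0.532 with an estimated correlation) passed in the same direction. Respiratory chain genes encoded in the nucleus (median 0.20) and ribosomal protein genes (median 0.17) were higher, and mitochondrially encoded genes lower (median -0.23). Each had an adjusted p of 0.532 with an estimated correlation. Without angiotensin II replicate 6 these medians were 0.065, 0.075 and -0.015, and the mitochondrially encoded list (adjusted p = 0.667) and the thalamus and midbrain list (adjusted p = 0.0502) no longer passed. Across genes, which are not independent replicates, the log2 fold change correlated with log2 gene length at a Spearman rho of -0.21. Among single genes of interest, the microglial gene Aif1 averaged 3.87 ± 0.709 FPKM under angiotensin II and 2.83 ± 0.670 under vehicle (adjusted p = 0.355), and the astrocyte gene Gfap 84.0 ± 15.2 and 70.6 ± 5.51 FPKM (adjusted p = 0.515). Log2 fold changes for Agt (0.08), Ace (0.05), Cd68 (0.14), Cldn5 (0.06), Vcam1 (-0.13) and Mbp (0.06) did not pass either, and Agtr1a, Cybb, Il1b and Ccl2 were below the filter.

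The effect of hydralazine under angiotensin II was tested by comparing mice given both drugs with mice given angiotensin II alone. In the hemisphere no gene passed with limma, and 760 had an unadjusted p under 0.05, where 837 are expected by chance. The 10 protein-coding genes with the smallest p, none of which passed, were Itm2a, Edn1, Cxcl12, Smo, Cbx1, Fam181b, Slc25a17, Adat2, Rbm15 and Higd1b. Edn1, which encodes the vasoconstrictor endothelin-1, averaged 3.87 ± 1.43 FPKM with both drugs and 1.34 ± 0.166 with angiotensin II alone (log2 fold change 1.17 ± 0.28, adjusted p = 0.851, higher in 6 of 6 libraries). Itm2a, a marker of brain endothelium, averaged 39.6 ± 4.33 and 30.5 ± 3.12 FPKM (log2 fold change 0.37 ± 0.08, adjusted p = 0.709). Of the 40 lists 5 passed: antigen presentation, extracellular matrix and respiratory chain genes toward lower values and immediate early and mitochondrially encoded genes toward higher values. None of these calls held with an estimated correlation. There the adjusted p was 0.774 for antigen presentation, matrix and mitochondrially encoded genes and 0.909 for the other lists. None of the 5 held without angiotensin II replicate 6, and the respiratory chain median then changed sign, from -0.08 to 0.04. With library weights 1 gene passed, Gm11223, named after its values were seen.

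The reversal of the angiotensin II effect was examined in the 12 hemisphere genes. With both drugs 11 of the 12 (91.7%) had a fold change of the opposite sign, but none passed, and 3 had an unadjusted p under 0.05. Both contrasts share the angiotensin II libraries, so opposite signs can arise without any drug effect. The share was 90.8% when the angiotensin II libraries were split into groups of 3, averaged over 20 splits. The 12 genes had been picked with all of these libraries, so the split does not remove that choice. The share was 92.8% in 100 simulations of unchanged groups, where both drugs do not differ from vehicle. Groups in which both drugs equal angiotensin II alone were not simulated. These shares therefore cannot tell a reversal from its absence. The interaction of angiotensin II and hydralazine, which tests the difference directly, called no gene (limma; 461 genes with an unadjusted p under 0.05). The immediate early genes Btg2 (interaction 1.102 ± 0.24 on the log2 scale) and Dusp1 (1.14 ± 0.27) were among the 5 named genes with the smallest p, each with an adjusted p of 1.0, with Sh3bgr, Mfap1b and mt-Co2. The immediate early gene list passed for the interaction (median 0.45, adjusted p = 6.03e-11; adjusted p = 0.595 with an estimated correlation), with 6 members higher when adjusted over the list alone. Circadian clock (median 0.14) and mitochondrially encoded genes (0.28) passed toward higher values, and antigen presentation (-0.21), extracellular matrix (-0.09) and glucocorticoid response genes (-0.13) toward lower values. These had an adjusted p of 0.595 or more with an estimated correlation. Without angiotensin II replicate 6 the immediate early and circadian lists passed and the other 4 did not.

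Mice given both drugs were also compared with vehicle. No hemisphere gene passed with limma (872 with an unadjusted p under 0.05). Genes with the smallest p included Podxl (9.64 ± 0.754 against 7.38 ± 0.547 FPKM, adjusted p = 0.173), Eln (2.61 ± 0.363 against 1.56 ± 0.214 FPKM, adjusted p = 0.223), Kdm6b (5.32 ± 0.473 against 6.72 ± 0.612 FPKM, adjusted p = 0.223) and Pglyrp1. Each lay beyond the vehicle mean in 6 of 6 libraries, which adds no support because the genes were picked by p from these libraries. Without angiotensin II replicate 6 in the shared estimate of the spread 3 genes passed, Podxl, Eln and Rcc1l, all higher. Without vehicle replicate 1 the count was 1, without vehicle replicate 3 it was 3, and with library weights it was 102, 68 higher and 34 lower. Immediate early genes were lower in 19 of 20 members (median -0.46, adjusted p = 3.41e-23; adjusted p = 0.113 with an estimated correlation), with 0 past the threshold over all genes tested and 16 lower when adjusted over the list alone. Endothelial genes had a median of 0.08 (adjusted p = 0.0167; adjusted p = 0.476 with an estimated correlation), with no member past the threshold over all genes tested and 4 higher when adjusted over the list alone. With library weights this list did not pass (adjusted p = 0.063). Ly6a averaged 29.9 ± 3.93 FPKM with both drugs and 19.7 ± 2.78 under vehicle (adjusted p = 0.223), and Pecam1, the endothelial adhesion molecule CD31, 4.42 ± 0.317 and 3.53 ± 0.404 (adjusted p = 0.313). Ribosomal protein genes were higher in 33 of 33 members (median 0.16; adjusted p = 0.471 with an estimated correlation) and choroid plexus genes lower in 11 of 11 (median -0.31; adjusted p = 0.462 with an estimated correlation). A further 6 lists passed with absolute medians of 0.13 or less. Respiratory chain, reactive astrocyte, interferon response and antigen presentation genes did so toward higher values, and circadian clock and hypoxia genes toward lower values, with an adjusted p of 0.462 or more with an estimated correlation.

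Hydralazine alone was compared with vehicle. No hemisphere gene passed with limma (279 with an unadjusted p under 0.05). Pparg, Dusp1, Btg2, Pigv and Zfp51 had the smallest p. Dusp1 averaged 11.7 ± 3.50 FPKM with hydralazine and 18.6 ± 3.47 under vehicle (adjusted p = 1.0). Immediate early genes were lower here too, in 19 of 20 members (median -0.29, adjusted p = 4.30e-16; adjusted p = 0.41 with an estimated correlation). Their list mean was 3.20 ± 0.25 per library with hydralazine against 3.55 ± 0.34 under vehicle (exact permutation p = 0.0714, adjusted over the lists 0.918). Choroid plexus (median -0.12) and circadian clock genes (median -0.06) passed toward lower values, both with an adjusted p of 0.798 with an estimated correlation. Under hydralazine, angiotensin II called no gene (limma; 501 with an unadjusted p under 0.05), and Sh3bgr, Podxl, Aif1, Pglyrp1 and Rnf39 had the smallest p. Aif1 averaged 3.82 ± 0.550 FPKM with both drugs and 2.57 ± 0.335 with hydralazine alone (adjusted p = 0.887). Of the lists 8 passed. Immediate early (median -0.19) and choroid plexus genes (-0.11) did so toward lower values, and ribosomal protein (0.10), respiratory chain (0.13), reactive astrocyte (0.11), complement (0.11), interferon response (0.08) and endothelial genes (0.05) toward higher values. None had an adjusted p under 0.741 with an estimated correlation, and with library weights the immediate early list did not pass (adjusted p = 0.0552). The angiotensin II effects without and with hydralazine share no library. Across all 16747 genes, which are not independent replicates, they correlated at a Pearson r of 0.18. Of the 12 called genes 11 had the same direction in both, as did 79.5% of the 200 genes with the smallest p without hydralazine. Both effects also carried a trend with gene length across genes (Spearman rho -0.207 without and -0.212 with hydralazine). Whether this shared trend gives the correlation was not tested. In the hippocampus the same correlation was 0.015 across 15267 genes, and 62.5% of the 200 genes chosen in the same way shared direction.

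**Figure D3:**
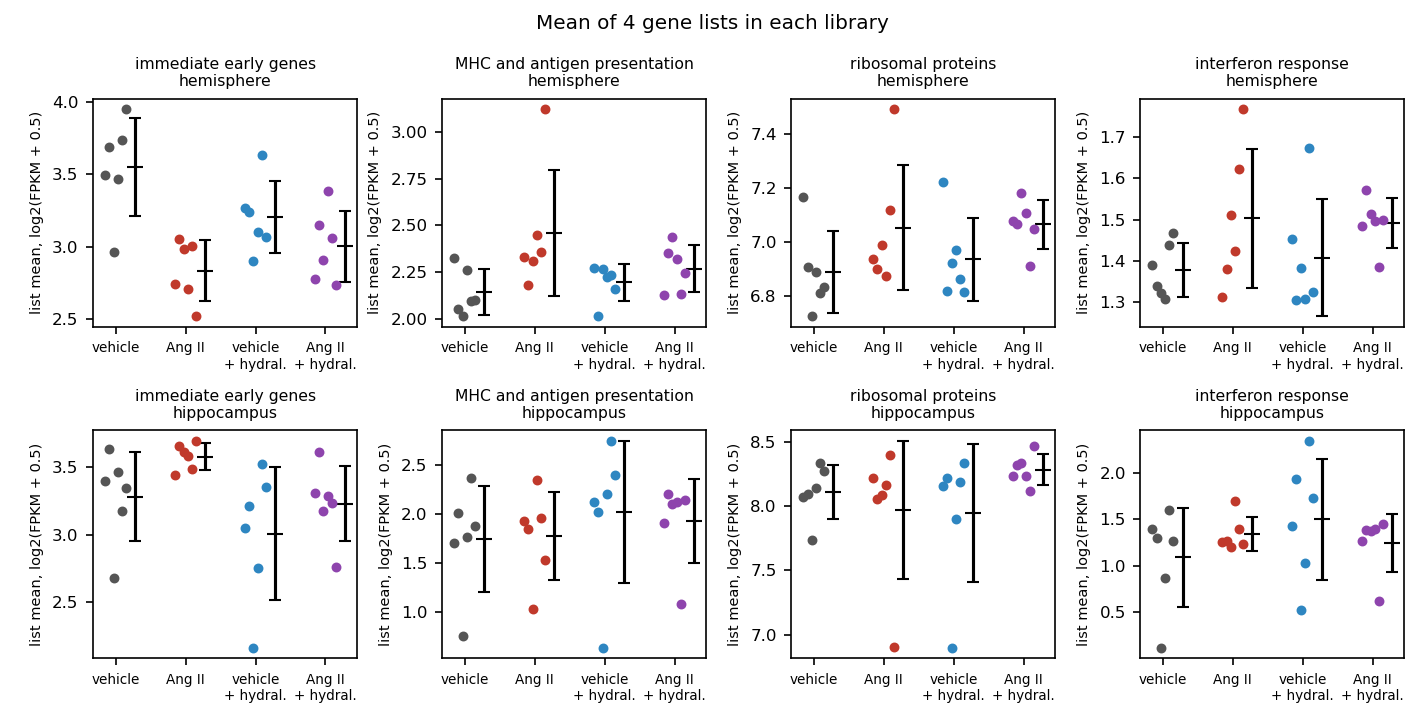
Mean log2(FPKM + 0.5) of the members of 4 gene lists in each library (y axis) for the 4 treatments, hemisphere in the upper panels and hippocampus in the lower; points are libraries and the bar beside them gives the mean ± SD (n = 6). Immediate early genes average 3.55 under vehicle and 2.84 under angiotensin II in the hemisphere, and 3.28 and 3.58 in the hippocampus.

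In the hippocampus angiotensin II changed no gene past the threshold (limma, 15267 genes tested). An unadjusted p under 0.05 was found for 210, where 763 are expected by chance. Genes with the smallest p, none passing, included Grasp, Btbd9, Rasgef1a, Htra2, Gal, Kdm8, Snd1, Gstp2 and Efhd1. Grasp, a scaffold of postsynaptic glutamate receptors, averaged 39.4 ± 4.29 FPKM under angiotensin II and 28.5 ± 5.21 under vehicle (adjusted p = 1.0). On simulated data of this depth and spread the test recovered 9 of 100 genes changed by 1.5-fold and 32 of 100 changed by 2-fold in the hippocampus, against 61 and 84 of 100 in the hemisphere. The 6 libraries with few genes lie in all 4 groups, and without them the count remained 0. Gfap (112.6 ± 8.88 against 107.2 ± 8.46 FPKM), Mbp (406 ± 57.0 against 435 ± 58.8 FPKM) and Cldn5 (46.9 ± 11.8 against 52.3 ± 11.6 FPKM) differed by less than the spread between libraries. Log2 fold changes for Agt (-0.72), Aif1 (0.39), Cd68 (-0.38), Ace (0.31) and Vcam1 (0.16) did not pass either. Of the lists 7 passed, none with an estimated correlation (adjusted p = 0.774 or more). Immediate early genes were higher in 15 of 20 members (median 0.26), with a list mean of 3.58 ± 0.10 per library under angiotensin II and 3.28 ± 0.33 under vehicle (exact permutation p = 0.0303, adjusted over the lists 0.606; without the libraries with few genes exact p = 0.111). Oligodendrocyte genes were lower in 17 of 18 members (median -0.17), blood genes (hemoglobins and Alas2) lower (median -0.57) and hippocampal neuron genes higher (median 0.14). Thalamus and midbrain genes were lower in 6 of 9 members (median -0.47), and their list mean was 3.47 in vehicle replicate 5, against 0.72 to 1.37 in the other 5 vehicle libraries. Ribosomal protein and respiratory chain genes passed toward lower values (medians -0.16 and -0.18), and the ribosomal protein list mean was 6.90 in angiotensin II replicate 6, against 8.05 to 8.40 in the other 5 libraries of its group. With library weights the ribosomal protein median was 0.014, and the immediate early, respiratory chain, ribosomal protein, hippocampal neuron and thalamus and midbrain lists did not pass (adjusted p = 0.0933 or more).

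Hydralazine under angiotensin II changed no hippocampal gene past the threshold (limma; 252 with an unadjusted p under 0.05), and Fxyd7, Jpt1, Carm1, Srrt, Khsrp, Arl2, Scand1, Brd3, Ctsd and Ap3b1 had the smallest p, each with an adjusted p of 1.0. Of the lists 7 passed, none with an estimated correlation (adjusted p = 0.501 or more). Immediate early genes were lower with both drugs in 19 of 20 members (median -0.38), with a list mean of 3.23 ± 0.28 per library against 3.58 ± 0.10 with angiotensin II alone (exact permutation p = 0.0108, adjusted over the lists 0.433). Ribosomal protein (median 0.32) and respiratory chain genes (median 0.30) were higher, the same lists in which angiotensin II replicate 6 stood low. Complement (median 0.22), antioxidant (0.12) and blood genes (0.70) passed toward higher values and heat shock genes (-0.12) toward lower values. Without the libraries with few genes the complement (adjusted p = 0.173) and antioxidant lists (adjusted p = 0.0902) did not pass, nor did they with library weights. Both drugs against vehicle called no gene (303 with an unadjusted p under 0.05; Grasp, Btbd9, Kcnk2, Srek1ip1 and Cplx2 had the smallest p), with ribosomal protein genes higher (median 0.15; adjusted p = 0.848 with an estimated correlation and 0.0676 without the libraries with few genes) and heat shock genes lower (median -0.14; adjusted p = 0.848 with an estimated correlation). The interaction of both drugs called no gene (366 with an unadjusted p under 0.05), and U2af2, Jpt1, mt-Nd4l, Ccl28 and Ap3b1 had the smallest p. Ribosomal protein (median 0.37), respiratory chain (0.38) and interferon response genes (-0.38) passed, each with an adjusted p of 0.979 with an estimated correlation. With library weights the ribosomal protein list did not pass (adjusted p = 0.106).

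Hydralazine alone was compared with vehicle in the hippocampus too. No gene passed (limma, 861 with an unadjusted p under 0.05, where 763 are expected by chance). Ap5b1, Ccl28, Sik1, Xaf1 and Sspn had the smallest p. Interferon response genes were higher in 13 of 20 members, with a median of 0.27 (adjusted p = 0.000135; adjusted p = 0.746 with an estimated correlation). Antigen presentation genes had a median of 0.29 (adjusted p = 0.00113; adjusted p = 0.746 with an estimated correlation), and oligodendrocyte genes a median of 0.09 (adjusted p = 0.882 with an estimated correlation). Ifit3, an antiviral gene induced by interferon, averaged 8.38 ± 3.67 FPKM with hydralazine alone, 2.83 ± 0.923 under vehicle (adjusted p = 0.677) and 2.94 ± 1.73 with both drugs (adjusted p = 0.649). Both drugs against hydralazine alone called no gene (limma; 911 with an unadjusted p under 0.05). Ifit3, Flot1, Cd9, Dnajc3 and Jpt1 had the smallest p, and the median over all genes was 0.15. In that contrast interferon response genes were lower (median -0.21; adjusted p = 0.803 with an estimated correlation), as were oligodendrocyte genes (median -0.21; adjusted p = 0.803 with an estimated correlation). Antigen presentation (-0.11), ribosomal protein (0.23) and glucocorticoid response genes (-0.01) passed as well, each with an adjusted p of 0.803 or more with an estimated correlation. Without the libraries with few genes the ribosomal protein (adjusted p = 0.0948) and glucocorticoid response lists (adjusted p = 0.283) did not pass, and with library weights the latter did not (adjusted p = 0.3). With library weights 6 genes passed, 1 higher and 5 lower, and without the libraries with few genes 0 did. The interferon list mean was 1.497 ± 0.65 with hydralazine alone and 1.09 ± 0.53 under vehicle, a difference within the spread of the libraries (exact permutation p = 0.264, and 0.0571 without the libraries with few genes). For both drugs against hydralazine alone the exact permutation p was 0.407, and 0.0159 without those libraries (adjusted over the lists 0.212).

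The hippocampus of vehicle mice was compared with the hemisphere to describe the tissues. Of 17643 genes tested 7442 passed (limma), 2244 higher and 5198 lower in the hippocampus. The excess of lower genes depended on the scaling. Median-of-ratios scaling gave 2239 higher and 5214 lower, quantile normalization 4043 and 3951, and removal of the gene length trend 3398 and 3648. The first set included genes of hippocampal neurons. Spink8 averaged 71.0 ± 14.8 FPKM in the hippocampus and 2.79 ± 0.365 in the hemisphere (log2 fold change 4.42 ± 0.19, adjusted p = 1.39e-23), and others were Klk8 (3.87), Lefty1 (3.78) and C1ql2 (3.66), the last a product of dentate granule cells. The second set included Cbln3 (-6.10), expressed in cerebellar granule cells, and Car8 (-5.73) and Pcp2 (-5.47), both markers of cerebellar Purkinje cells. Gabra6, another cerebellar granule cell gene, averaged 29.5 ± 3.59 FPKM in the hemisphere and was listed at 0 in all 6 hippocampal libraries. The hippocampal neuron (median 2.06), cerebellum (-4.06), striatal neuron (-2.28) and cortical neuron (-1.20) lists passed, and each held with an estimated correlation. The median over all genes was -0.21. Ribosomal protein genes were higher in the hippocampus in 33 of 33 members (median 1.29; adjusted p = 0.097 with an estimated correlation). Of them 31 passed over all genes tested and 32 when adjusted over the list alone. In all 16 lists passed, and the other 12 had an adjusted p of 0.073 or more with an estimated correlation. The ribosomal protein list mean in hippocampal angiotensin II replicate 6 was 6.90, close to the hemisphere vehicle mean of 6.89 ± 0.15. Without the 6 libraries with few genes 11245 genes passed, 4201 higher and 7044 lower, and with library weights 12483 did.

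The difference between regions of the angiotensin II effect was tested directly in all 48 libraries. No gene passed (limma, 516 with an unadjusted p under 0.05, where 882 are expected by chance). Arc (difference 2.33 ± 0.44 on the log2 scale, adjusted p = 0.0721), Junb (1.36 ± 0.33), Nr4a1 (1.31 ± 0.31), Tnfrsf25 (1.27 ± 0.34) and Itgb1bp1 (-0.55 ± 0.15) had the smallest p. Arc passed without the 6 libraries with few genes, with quantile normalization and with library weights, and its adjusted p ranged from 0.0203 to 0.722 over 8 alternatives. No gene passed without the 6 libraries and hippocampal angiotensin II replicate 6. The count was 1 without hemisphere vehicle replicate 3, hippocampal vehicle replicate 2 or hippocampal vehicle replicate 3. Immediate early genes as a list differed between regions in 19 of 20 members (median 0.80, adjusted p = 7.71e-20), and this call held with an estimated correlation (adjusted p = 0.004), with 0 members past the threshold over all genes tested and 10 higher when adjusted over the list alone. For the hydralazine effect under angiotensin II no gene passed (limma; 433 with an unadjusted p under 0.05; Jpt1, Brd3, Fxyd7, Sh3bgrl3 and Dnlz had the smallest p), and no list did with an estimated correlation (adjusted p = 0.682 or more).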

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

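The tests of depth, treatment groups, vehicle libraries, differences between regions, choroid plexus content, the amount of blood and antigen presentation without angiotensin II replicate 6 were chosen after the result or the values behind it were seen. The tests of missing genes, gene length and the correlation with blood were chosen after the data were seen but before their own results, and the counts over other splits were set before they were run. Of 128 sets of 6 libraries, 28 held a library that lay apart by Dixon's 95% critical value. Chance gives about 1 in 20, or 6.4 on average. The sets reuse the same 8 groups over many measures, so they are not independent. Some libraries lay apart in several measures, among them angiotensin II replicate 6 in each region. Whether 28 exceeds chance was therefore not tested.

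Hippocampal libraries differed in genes listed above 0: angiotensin II replicate 3 listed 14043 (others 21986 to 23044) and replicate 5 of both drugs 12915 (others 18914 to 22073), and these belong to the 6 libraries with fewer than 16000 genes. Shallow sequencing is argued against: thinned to 1000000 reads, the other 18 hippocampal libraries still listed at least 15796 genes, more than the 15684 of the fullest of the 6 at full depth. Treatment is argued against as the sole source, because all 4 groups hold at least 1 of the 6. Vehicle and vehicle plus hydralazine hold 2 each, and angiotensin II and both drugs 1 each. An unequal rate between treatments was not tested. Most of the 6 bear number 3 or 4, so a batch that follows the number is not excluded. Replicate 3 of both drugs, kept in the fits without the 6, listed 18914 genes. Of these 1.74% had 1 read, against 1.3% to 1.6% in the 6. Few RNA molecules amplified many times may be the source, as a hypothesis. Among 838 genes at 2 to 3 reads per 1000000, 19.1% to 89.5% were missing from these libraries and at most 0.2% from any other. Genes missing from both libraries of a pair were close to the product of the separate shares (median ratio 1.06, highest 1.15). A random loss would give this. The ratio of a pair cannot exceed 1 divided by its larger share, so the median set to count against this cause was out of reach. Where most genes are missing, the ratio therefore says little about whether the same genes were lost. What limited the molecules stays open.

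Immediate early genes were lower in the hemisphere of angiotensin II mice than of vehicle mice (exact permutation p = 0.00866, adjusted over the lists 0.0866). The list did not pass there with an estimated correlation. Between regions it differed by a median of 0.799. Choroid plexus content, as far as its list mean measures it, is argued against as the whole source of the lower hemisphere values. The difference in the list mean was -0.72 ± 0.15 (SE) without and -0.661 ± 0.17 with the choroid plexus list mean as a covariate. Vehicle libraries that stand apart are argued against as the whole source, since angiotensin II libraries were also lower than those with hydralazine alone (difference -0.37, exact permutation p = 0.0195, adjusted over the lists 0.216), though hydralazine alone also lay below vehicle. An angiotensin II effect shared by both regions is argued against by the test between regions (camera adjusted p = 0.004 with an estimated correlation). That test used all libraries, and the estimated correlation was not run without the 6 libraries with few genes. In the hippocampus by itself the list did not pass with an estimated correlation or with library weights. An effect of angiotensin II on the hemisphere, or a difference in handling or time of collection that followed the groups, may remain, and no label gives the latter.

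Antigen presentation genes were higher in the hemisphere of angiotensin II mice, though the list did not pass with an estimated correlation. Angiotensin II replicate 6 had a list mean of 3.12 (others 2.18 to 2.45). That library is argued against as the whole source, since the list mean still differed by 0.185 without it (exact permutation p = 0.0325). A gene length trend is argued against as the whole source, since the list median was 0.249 after its removal (exact permutation p = 0.00866). That test kept angiotensin II replicate 6, and the trend and this library were not removed together. Blood in the tissue followed the list within groups over the other 23 libraries (Pearson r = 0.564, permutation p = 0.00512; Spearman rho = 0.515, p = 0.0132; r = 0.48 without the 2 libraries farthest from the median), but without replicate 6 the blood list mean was no higher under angiotensin II (difference -0.1; 0.144 with all libraries), so there it accounted for -0.017 (95% bootstrap interval -0.104 to 0.032) of the difference of 0.185. As a hypothesis, angiotensin II may raise antigen presentation genes in the hemisphere, although the exact test adjusted over the 40 lists gave 0.121 with all libraries and 0.26 without that replicate.

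Other libraries apart from their group are given as values. In the hemisphere, angiotensin II replicate 6 listed 23165 genes (others 24410 to 24782), had 2.77% mitochondrial reads, a respiratory chain list mean of 7.51 (others 6.79 to 6.999), a mitochondrially encoded list mean of 7.71 (others 9.24 to 9.53) and 5.95 FPKM of Adrb1 (others 7.29 to 7.78). Vehicle replicate 1 listed 23693 genes, had 7.22% mitochondrial reads and a mitochondrially encoded list mean of 9.69; vehicle replicate 3 had 19.6 FPKM of Junb and 0.929 FPKM of Msantd1. Replicate 1 of vehicle plus hydralazine had a respiratory chain list mean of 7.06, replicate 1 of both drugs 23.5 M reads (M stands for 1000000) and replicate 4 of both drugs 9.38 FPKM of Btg2. In the hippocampus, angiotensin II replicate 6 had 5.74% mitochondrial reads and list means of 6.90 for ribosomal proteins, 6.65 for the respiratory chain and 9.34 for mitochondrially encoded genes; vehicle replicate 1 had a mitochondrially encoded list mean of 10.3, and angiotensin II replicate 3 had 14.44 M reads. Replicate 3 of vehicle plus hydralazine had 1.21 M reads and list means of 0.637 for antigen presentation, 6.90 for ribosomal proteins and 7.03 for the respiratory chain; replicate 5 of both drugs had list means of 1.08 for antigen presentation and 0.63 for the interferon response.

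List tests of the difference between regions passed for 20 lists and contrasts, as medians in the hippocampus less the hemisphere. For the angiotensin II effect these were immediate early genes (0.80), choroid plexus (0.58), circadian clock (0.24), hippocampal neurons (0.23), heat shock (0.17), oligodendrocytes (-0.12), antigen presentation (-0.18), ribosomal proteins (-0.32), respiratory chain (-0.37) and blood (-0.52). For the hydralazine effect under angiotensin II they were respiratory chain (0.35), pericytes and smooth muscle (0.33), ribosomal proteins (0.30), antigen presentation (0.26), complement (0.12), antioxidant defence (0.12), mitochondrially encoded genes (-0.23), heat shock (-0.25), choroid plexus (-0.43) and immediate early genes (-0.44). With an estimated correlation the immediate early genes of the angiotensin II effect passed and the others did not.

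Other splits of the same libraries, 100 per comparison with the real one included, bear on chance. For angiotensin II against vehicle in the hemisphere, 1 of 100 splits, the real one, gave 12 genes or more, and the highest other gave 3. Chance is argued against for the count, at the smallest share that 100 splits can give. The count was nonetheless 0 without angiotensin II replicate 4, vehicle replicate 5 or vehicle replicate 6, and 2 with only the 2 groups fitted. For the hippocampus against the hemisphere 1 of 100, the real one, reached 7442, and the highest other gave 4530, so chance is argued against for this count too. For the 13 comparisons with 0 genes all 100 splits give as many whatever the data, so these counts say nothing about chance. The highest other count was 14 for both drugs against vehicle in the hemisphere and 1 or 0 elsewhere.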

How the results depend on the processing

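Fits without the doubted libraries or the gene length trend, and list tests with library weights, were chosen after seeing the data. Why a value moved was not tested. The 12 genes for angiotensin II against vehicle in the hemisphere became 38 with library weights, 4 without a filter, 2 with only the 2 groups, 5 with the replicate block, 0 with the choroid plexus covariate (Arc -1.70 ± 0.33 in place of -1.82 ± 0.31, Neat1 0.38 ± 0.07 in place of 0.44 ± 0.07) and 0 to 20 with a library left out; 10 to 14 were called under the remaining settings. The numbers in the titles did not pair every library by correlation: same-number deviations correlated at -0.208 to 0.473 in the hemisphere (median 0.004; other numbers -0.306 to 0.317, median 0.001) and -0.2 to 0.26 in the hippocampus (median 0.068; others -0.244 to 0.286, median 0.025). Between regions same-number deviations correlated at -0.207 to 0.041 (median -0.009), others at -0.116 to 0.166 (median 0.002), and 5 of 24 libraries correlated best with their own number. A mouse or batch shared by number is not excluded: 5 of the 6 libraries with few genes bear number 3 or 4. Angiotensin II replicate 6 stood apart in both regions, but not always in the same direction. Its mitochondrial share was low in both. Its respiratory chain list mean was high in the hemisphere (7.51, others 6.79 to 6.999) and low in the hippocampus (6.65, others 7.595 to 7.907). The replicate block also gave 1 gene each for hydralazine alone against vehicle and for both drugs against hydralazine alone in the hemisphere. With library weights both drugs called 1 gene against angiotensin II and 102 against vehicle in the hemisphere and 6 against hydralazine alone in the hippocampus. Both drugs against vehicle in the hemisphere gave 3 without angiotensin II replicate 6, and 0 to 3 with a library left out (1 without vehicle replicate 1, 3 without vehicle replicate 3). The region difference of the angiotensin II effect gave 1 gene with quantile normalization or without the 6 libraries with few genes (0 also without hippocampal angiotensin II replicate 6), 3 with library weights and 0 to 1 with a library left out (1 without hemisphere vehicle replicate 3 or hippocampal vehicle replicate 2 or 3). The hippocampus against the hemisphere gave 12483 genes with library weights, 11245 without the 6 libraries, 11433 also without hippocampal angiotensin II replicate 6, and 6910 to 7422 with a library left out. The other comparisons stayed at 0 with each library left out. Of 47 list calls in the hemisphere, 27 in the hippocampus and 36 between regions, an estimated correlation left 0, 0 and 5. By itself fry called 2, 0 and 23, and it kept 19 of the 110 calls. Library weights gave 52 and the fit without the 6 libraries 45 in the hippocampus, but lost 9 and 5 of the 27 calls. List medians that turned were mitochondrially encoded genes for angiotensin II in the hemisphere (0.008, weights), respiratory chain for hydralazine under angiotensin II there (0.055, weights; 0.044 without angiotensin II replicate 6) and ribosomal proteins for angiotensin II in the hippocampus (0.014, weights). Genes that turned, none called, were Mbp (-0.039, quantile) and Vcam1 (0.004, weights) for angiotensin II in the hemisphere, and Gfap for hydralazine under angiotensin II (0.073, hemisphere, weights; -0.102, hippocampus, quantile). In simulated data the hippocampal test recovered 32 of 100 genes changed by 2-fold; the parts of depth and of the spread between libraries in this were not separated.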

Other observations

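Values of the vascular genes Podxl and Eln in the 4 hemisphere groups are set side by side here. Podxl averaged 9.56 ± 0.614 FPKM with angiotensin II and 9.64 ± 0.754 with both drugs, against 7.38 ± 0.547 under vehicle and 7.80 ± 0.780 with hydralazine alone. Eln averaged 2.76 ± 0.717 and 2.61 ± 0.363 FPKM with angiotensin II and with both drugs, against 1.56 ± 0.214 under vehicle and 1.88 ± 0.248 with hydralazine alone. Podxl with both drugs exceeded the mean of hydralazine alone in 6 of 6 libraries (log2 fold change 0.29 ± 0.07, limma adjusted p = 0.592).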
